A study of Drosophila melanogaster with 4 samples.

How the data were processed

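Chromatin of Drosophila melanogaster embryos labelled 0 to 8 h was immunoprecipitated with an anti-Cmi antibody (2 libraries), and input DNA was sequenced beside it (2 libraries). Per the submitters' processing notes, CASAVA 1.7.0.2 and 1.7.0.3, BWA and MACS2 were used with the genome build BDGP5. The role and order of these tools are not given there, and the versions of BWA and MACS2, the thresholds, and whether the replicates were pooled or called separately are not given in the sources used here. Per the file header, the peaks are placed on FlyBase release 5, and the file names MACS as the caller. The deposited file is 1 list of 3110 peaks with a sequence name, a start, an end and 1 score per peak, and it has no columns for single libraries. Coordinates are 1-based, as in the file.

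The authors' deposited score carries no scale in the file, and its scale was read from the values. The list holds 992 distinct scores, and 84 values were each shared by 5 or more peaks. A Poisson background was sought whose tail, as the negative log10 of the probability of a given read height or more, passes through these recurrent values. A background of 31.1 reads matched 77 of the 84 values within 0.0061, while no background more than 1 read away, in a scan from 5 to 120 reads, matched more than 11, and the best evenly spaced series, which a linear fold of whole reads would give, matched 22. The tolerance and the minimum of 5 peaks were set after the scores had been examined and a coarser scan had been run. The other 7 recurrent values count as off the series. Of these, 8.11 (42 peaks), 38.47, 39.72 and 66.45 lie within 0.015 of a step, so the shares on the series were also computed with tolerances of 0.01 and 0.015. The score is therefore read as −log10 of a Poisson p-value, not adjusted for multiple tests. A score on this series is what a whole number of reads gives against a single background for the whole genome; MACS uses a higher local background where the local input exceeds it. On the major arms 1988 peaks lay on the series, with a median height of 2.73 times the background. Width and read height are tied through the caller, so a positive correlation of score and width follows in part from the calling. Scores were compared only between peaks of this list. The depth of the libraries is unknown. Wilson intervals cover counting error of peaks only.

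Peaks were counted by midpoint. Sequences 2L, 2R, 3L, 3R, 4 and X were taken as the major arms, and Uextra, U and the Het sequences, which collect unplaced and heterochromatic sequence of release 5, were kept out of the comparisons between arms. Arm lengths of release 5 were not used here, so each arm was taken from the first to the last window with a peak. Peak density was compared in windows of 100 kb with two-sided permutation tests of the mean (100000 permutations), with Benjamini-Hochberg adjustment over the 6 arms, and 95% intervals of ratios came from 2000 resamples of windows. The spacing of peaks was compared with 1000 uniform random placements within the span of each arm. Score and width were correlated across peaks with 100000 permutations. The 20 peaks with the highest scores and the 10 windows of 100 kb with most peaks are named, a rule set before the data were examined for the case that no annotation of the same build was at hand. The windows were ranked on the major arms only.

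The alternatives set before the data were examined were windows of 50 and 200 kb, only the peaks ranked above the median or above the upper quartile of the score, joining of peaks within 1 kb for the densities, neighbour distances of 2 and 10 kb, and the correlation without the 2 farthest peaks. Rotation of the arm labels, windows of 1 Mb, joining and placement within 1 Mb stretches for the spacing, the split of the correlation by sequence, wider tolerances for the score series, stretches of 1 Mb in the tests that bear on X, and the comparison of widths at matched scores were added after seeing the data. Subsets of peaks were counted in the windows of the full list, which replaced a first version in which a subset could shorten an arm and which had already been run. The gene table at hand is of Release 6, another build than that of the peaks, and was used only to look up the symbol of CG5591. The planned comparisons with transcription start sites, annotation classes, gene lists, the homeotic complexes and sequence motifs were therefore not run.

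The tests were tested on simulated data with 200 draws per setting. With no difference and no clustering simulated, 6.5% of the tests of X against the autosomes and 5.0% of the spacing tests fell below 0.05. With no difference and peaks clustered about as observed (median variance over mean 3.91, correlation of neighbouring windows 0.135), the test of single windows fell below 0.05 in 21% of draws and the rotation in 4.5%, and 1.5% of draws reached the observed ratio or a lower one. Permutations and resampled intervals of single windows ignore this clustering. This setting was added after seeing the data. With X at 0.75 of the autosomal density and no clustering, the test of X fell below 0.05 in 100.0% of draws, and the median ratio recovered was 0.75. A difference with peaks clustered about as observed was not simulated. The power of the window test and of the rotation in such data is therefore unknown. With a simulated background of 25.4 reads the series was recovered at 25.4, and 2.74% of the peaks simulated with a raised background were placed on it by chance. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.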

Results

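Binding of Cmi to chromatin was profiled by ChIP-seq in Drosophila melanogaster embryos of 0 to 8 h. Cmi (Cara Mitad, CG5591) is listed under the symbol Lpt in the release 6 gene table. It is a subunit of the Trithorax-related complex, which methylates histone H3 on lysine 4 and acts at enhancers. The strain carried a transgene of extradenticle (exd), a cofactor of the Hox proteins, fused to GFP. The labels describe 2 libraries immunoprecipitated with a polyclonal rabbit antibody against Cmi and 2 libraries of input DNA. The extraction protocol in the same labels describes an older collection window and a different stock, and the stage and strain fields of the samples were followed here. A single list of 3110 peaks represents the experiment, with a position on FlyBase release 5 and a score for each peak. It holds no value per library, so the depth of the libraries is unknown and the agreement between the replicates was not analysed. The peaks were compared with the chromosomes they lie on, and the p-values describe the placement of the peaks in this 1 list, not the variation between embryo collections. Peaks are named by position, because genes were not assigned to them here.

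Cmi peaks were found on all 6 major arms, 2679 peaks in all or 86.1% of the list. 3R held 685 peaks, 2R 612, 3L 540, 2L 429, X 395 and the small chromosome 4, which is largely heterochromatic, 18. The peaks of the major arms were narrow, with a median width of 448 bp (quartiles 294 and 741.5 bp), and together covered 1636 kb. Of these peaks 381, or 14.2%, were wider than 1 kb. The median score was 13.99 (quartiles 10.3 and 22.5), and the scores of the major arms ran from 6.09 to 209.5. Of the 1186 windows of 100 kb between the first and the last peak of each arm, 411 held no peak, while 42 held 10 or more.

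**Figure D1:**
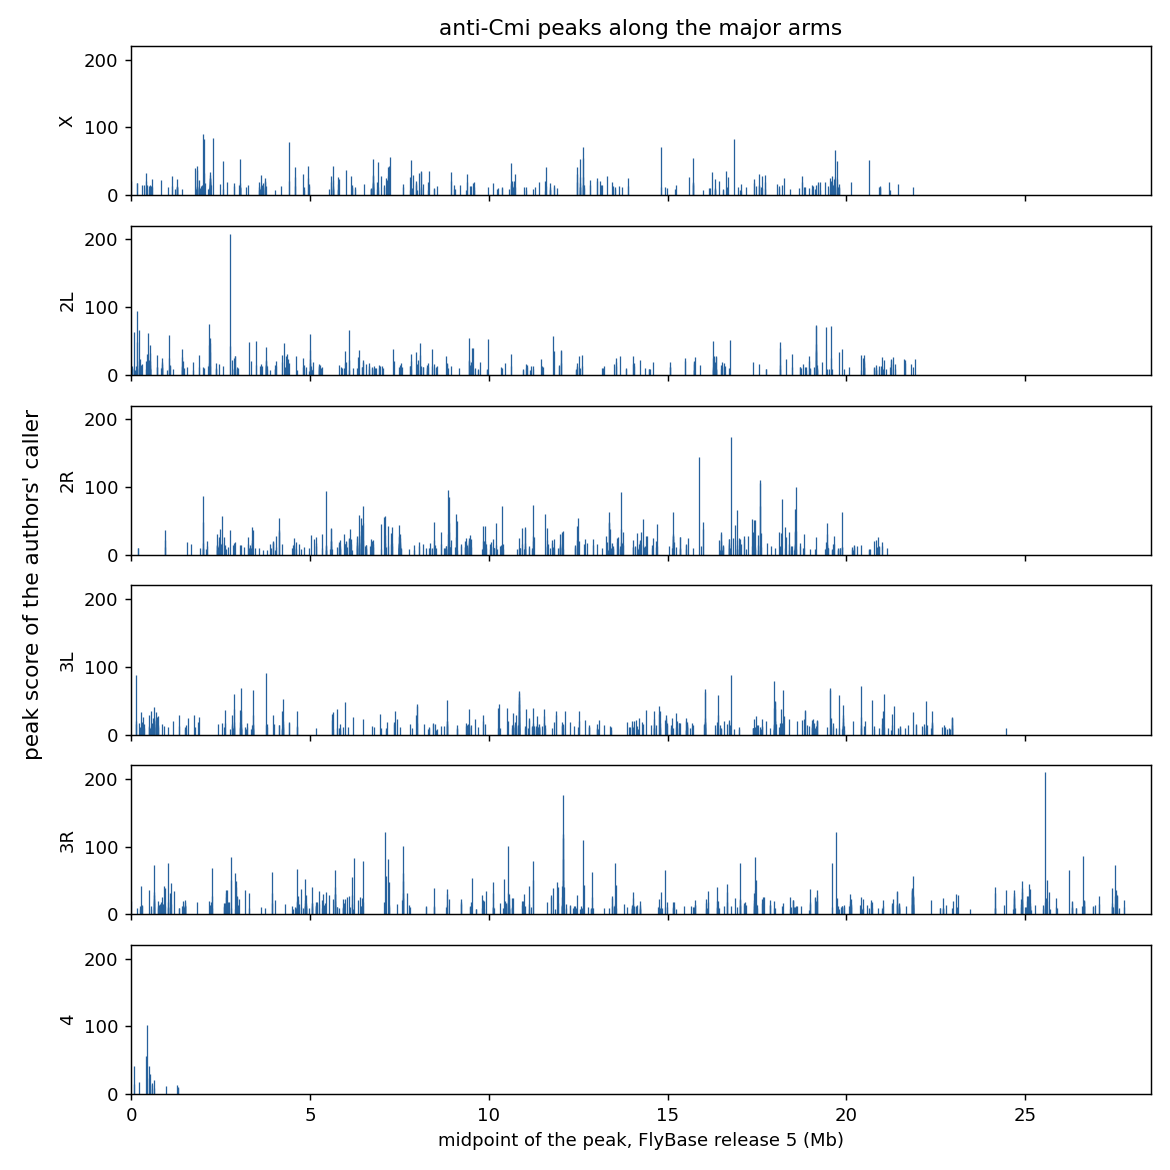
Each vertical line is 1 peak of the major arms, at the midpoint of the peak on FlyBase release 5 (Mb, horizontal axis), with the score given by the authors' caller as its height (vertical axis, no replicates). The highest peak, with a score of 209.5, lies on 3R.

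The arms differed in peaks per window, but no arm stood out in the test that kept neighbouring windows together. 2R was the most densely occupied arm, with 2.90 ± 3.47 peaks per 100 kb window (SD, n = 211 windows) against 2.12 ± 2.87 on the other major arms (n = 975 windows), a ratio of 1.37 (95% interval 1.13 to 1.63, windows resampled). This difference passed a two-sided permutation test of windows (p = 0.0007, adjusted p = 0.0042 over 6 arms, Benjamini-Hochberg). X was occupied less densely than the other major arms, with a ratio of 0.764 (95% interval 0.612 to 0.926, permutation p = 0.013, adjusted p = 0.0395). Neither 2L (ratio 0.837, permutation p = 0.092, adjusted p = 0.18), 3L (0.975, p = 0.79, adjusted p = 0.79), 3R (1.12, p = 0.19, adjusted p = 0.26) nor chromosome 4 (0.566, p = 0.22, adjusted p = 0.26) passed the same test. The test treats windows as independent, but neighbouring windows were correlated (0.13), which can make its p-values too small. The arm labels were also rotated along the joined arms, which keeps neighbouring windows together. The calls for 2R (permutation adjusted p = 0.37) and X (0.42) were then lost. How often the rotation detects a true difference was not simulated, so the lost calls do not show equal densities. Windows of 1 Mb ended both calls too (0.071 and 0.19), and that of X was also lost in windows of 200 kb (0.068) and among the peaks ranked above the median (0.052) or the upper quartile (0.057) of the score. Over all alternatives the adjusted p ran from 0.0003 to 0.37 for 2R and from 0.010 to 0.42 for X.

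The X chromosome, on which transcription is raised in males by dosage compensation, was then set against the 4 large autosomal arms. No correction was made for the number of copies of X in the embryos, so an effect of copy number on the density cannot be told apart here. X held 1.80 ± 2.46 peaks per 100 kb (SD, n = 219 windows) and the autosomal arms 2.38 ± 3.11 (n = 953 windows). The ratio of X to autosomes was 0.759 (95% interval 0.616 to 0.924), which passed the two-sided permutation test of windows (p = 0.011). The median score was 13.99 on both X and the autosomes. The median width was 413 bp on X and 454 bp on the autosomes, a difference that was not tested. Only called peaks enter these medians, so equal median scores do not show equal signal. The difference in density did not pass when the arm labels were rotated (permutation p = 0.14) or in windows of 1 Mb (p = 0.0504), and over all alternatives p ran from 0.0029 to 0.14. In simulations with equal densities and peaks clustered about as observed, the test of single windows fell below 0.05 in 21% of draws and the rotation in 4.5%, so the p of 0.011 is too small. A ratio as low as that observed or lower came up in 1.5% of these draws, a one-sided share that depends on the clustering assumed. On X, 95.4% of the peaks (95% Wilson interval 92.9 to 97.1) had a score from 1 common series of values that matches whole read heights against a single background, compared with 70.5% on the autosomal arms (68.6 to 72.4). With a wider tolerance of 0.015 for this match, chosen after seeing the data, the shares were 99.2% and 74.4%.

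**Figure D2:**
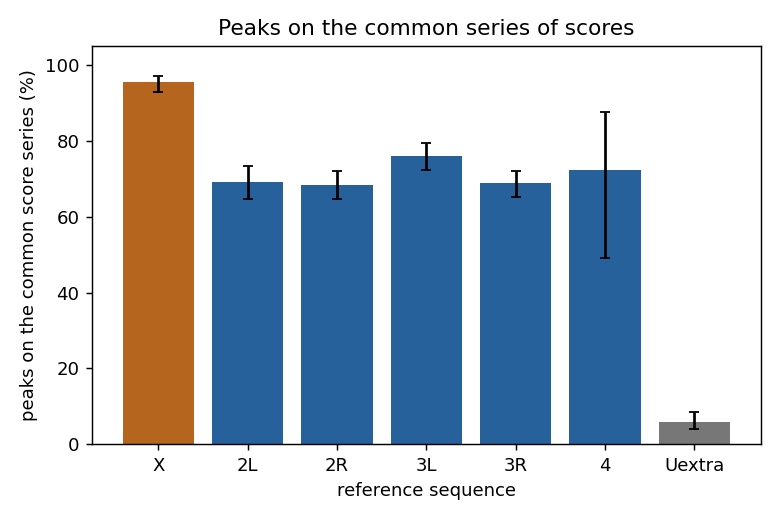
Share of the peaks of each reference sequence whose score lies on the common series of values (vertical axis, percent), with bars for the sequences on the horizontal axis and 95% Wilson intervals as error bars. The share was 95.4% on X, between 68.5% and 76.1% on the large autosomal arms, and 5.76% on Uextra.

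Cmi peaks lay in groups along the arms. Of the 2679 peaks of the major arms, 1712 or 63.9% (95% Wilson interval 62.1 to 65.7) had another peak within 5 kb, midpoint to midpoint. The comparison was uniform random placement of as many peaks on each arm, which ignores genes, repeats and stretches where reads cannot be placed. It can show only that the peaks are not spread uniformly. Such random placement gave 20.7% on average and at most 23.6% in 1000 draws (n = 2679 peaks, two-sided p = 0.000999, the smallest that 1000 draws can give). Each large arm showed this spacing, from 60.1% on 2L to 67.4% on 3R, and on chromosome 4 it was 9 of 18 peaks (adjusted p = 0.0012 for each of 2L, 2R, 3L, 3R and X, and 0.004 for chromosome 4 with n = 18 peaks, two-sided, by random placement). Chaining peaks at this distance gave 967 single peaks and 565 groups, of which 70 held 5 or more peaks and together 490 peaks, or 18.3% of those on the major arms. When peaks with edges within 1 kb were joined, the share with a neighbour fell to 35.0% of 1974 regions, against 15.7% for random placement, a ratio of 2.22 where the single peaks gave 3.09.

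The fullest groups each held 16 peaks. On 2R one ran from 7480785 to 7502898, where its peaks covered 35.7% of the stretch, and on 3L the other ran from 613595 to 641295 with 44.7% covered. Groups of 12 peaks lay on 3L at 10835882 to 10855546 (59.0% covered), on 2R at 2476484 to 2500621 (26.6%) and on 3R at 27522922 to 27533236 (69.0%). A group of 13 peaks lay on 3L at 17992493 to 18015892. The fullest group on X held 11 peaks between 2187655 and 2202873, and the fullest on 2L held 10 peaks between 507227 and 523935.

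**Figure D3:**
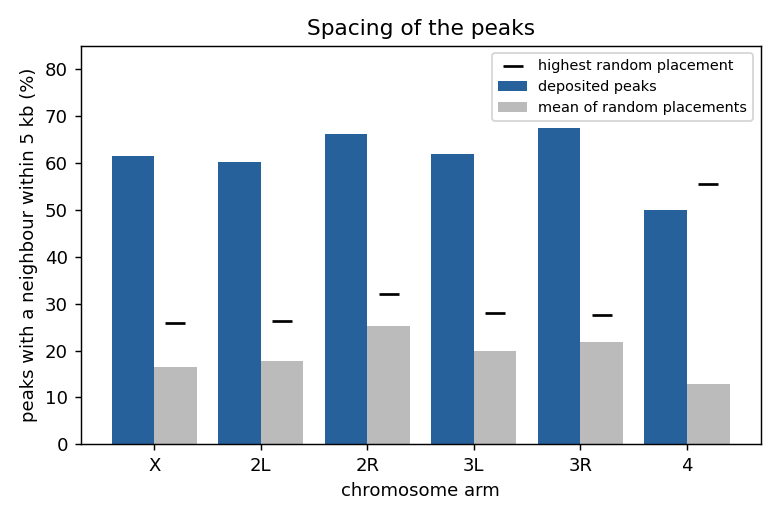
Share of peaks with another peak within 5 kb (vertical axis, percent) on each major arm (horizontal axis), for the deposited peaks and for the mean of 1000 random placements, with the highest placement as a short line. On the large arms the deposited peaks reached 60.1% to 67.4%, above the highest placement of each; on chromosome 4 they reached 50.0%, below the highest placement of 55.6%.

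Of the 20 peaks with the highest scores, 8 lay on 3R, 5 on 2R, 1 on 2L, 1 on chromosome 4 and 5 on the unplaced sequence Uextra. None lay on X, whose highest score was 90.53. The highest score, 209.5, belonged to a peak of 2511 bp on 3R at 25541568 to 25544078. The next, 207.1, belonged to a peak on 2L at 2749308 to 2754705, which at 5398 bp was also the widest of the list. A narrow stretch of 3R held 3 of the 20, at 12060156 to 12063398 (score 118.4), 12065930 to 12068837 (113.2) and 12075015 to 12076688 (176.1). On 2R, the peaks at 16771599 to 16772352 (174.1) and 15884529 to 15885601 (144.6) were also among the 20. On 2R a pair lay at 17590039 to 17591653 (106.3) and 17593269 to 17595587 (109.7), and a further peak on 2R lay at 18576927 to 18578811 (100.4). The remaining 4 on 3R were at 19711697 to 19713437 (121.9), 7094164 to 7095153 (121.1), 12624388 to 12624864 (109.7) and 10539597 to 10541010 (101.3). The peak on chromosome 4 lay at 445189 to 445650 (102.1), with a width of 462 bp. The highest on Uextra were at 28213639 to 28214234 (106.46), 27872319 to 27872868 (103.09) and 27076650 to 27077299 (102.17). Its other peaks among the 20 were at 28588110 to 28588653 (101.85) and 27712087 to 27712638 (101.35).

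Among the windows of 100 kb on the major arms, the 10 with most peaks lay on the autosomes. Uextra, which was left out of this ranking, held up to 35 peaks in 1 window. On 3R, the windows starting at 17400001 and 27500001 each held 22 peaks, 9.74 times the mean of all windows of the major arms (2.26 peaks). On 3L the window starting at 600001 and on 2R the window starting at 2400001 each held 21. Windows on 3R starting at 12000001, which contains the stretch with 3 of the highest scores, and at 21800001 each held 17. The other 4 windows were on 2R, starting at 19400001 and 9400001 with 15 peaks each and at 18500001 and 7500001 with 14 each.

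Score and width rose together, and the caller ties them, since both depend on the height of the reads. Across all 3110 peaks, which are not independent replicates, score and width were correlated with Pearson's r of 0.50 and Spearman's rho of 0.55 (permutation adjusted p = 1e-05 for both, the smallest that 100000 permutations can give, over 8 correlations). Leaving out the 2 peaks farthest from the median score gave r = 0.48. The relation was closer on the major arms alone (r = 0.67, rho = 0.76, n = 2679 peaks) than on Uextra (r = 0.44, rho = 0.37, n = 417 peaks), though the difference between these correlations was not tested. At scores above 30 and up to 50, the median width was 995 bp on the major arms (quartiles 747 and 1447 bp, n = 261 peaks) and 350.5 bp on Uextra (250.2 and 406.2 bp, n = 232 peaks), a 2.84-fold difference (two-sided permutation p = 0.0001, the smallest that 10000 permutations can give, adjusted p = 0.000167 over 5 score ranges). The ratio was smaller at scores above 10 and up to 20 (1.28, permutation adjusted p = 0.0444). It was 2.14 up to 30 (adjusted p = 0.000167), 3.14 above 50 and up to 80 (0.000167), and 2.98 above 80 (0.00362), by the same permutation test. These ranges were chosen after the data had been seen, and the test treats peaks as independent, so its p-values may be too small.

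**Figure D4:**
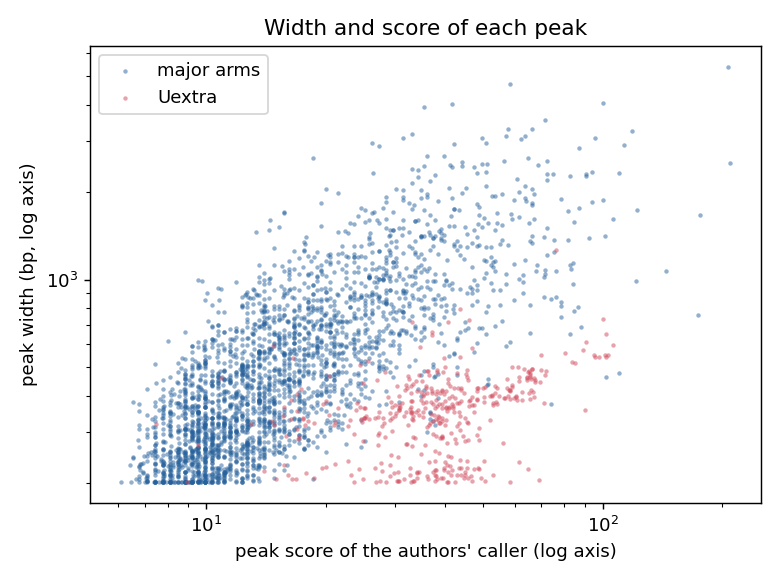
Each point is 1 peak, with the score of the authors' caller (horizontal log axis) and the width in bp (vertical log axis), for the major arms and for the unplaced sequence Uextra. At scores above 30 and up to 50 the peaks of Uextra lie near their median of 350.5 bp, below most peaks of the major arms, whose median is 995 bp.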

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

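All tests of this part were chosen only after the results they concern had been seen.

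The list holds 417 peaks on Uextra, 13.4% of all peaks (95% Wilson interval 12.3 to 14.7), 10 on U and 4 on the Het sequences (1 each on 2LHet, 2RHet, 3RHet and YHet). These sequences were not part of the comparisons between arms and drew attention because any peaks are called on them at all. The Uextra peaks were not spread evenly: 1 stretch of 1 Mb, from 28000001 to 29000000, held 194 of them, while the median of the other stretches with peaks was 6. Uextra collects unplaced sequence, so such a stretch need not be 1 place in the genome. The Uextra peaks were strong for their width, and 333 of the 417 (79.9%) lay above the upper quartile of the whole list, compared with 16.2% of the peaks on the major arms.

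Weak calls near the score threshold are argued against as the source of the Uextra peaks, because their median score was 24.3 above that of the major arms (two-sided permutation p = 0.0001, the smallest that 10000 permutations can give). A candidate explanation is multi-copy sequence with raised input: 5.76% of the Uextra peaks (95% Wilson interval 3.90 to 8.42) had a score on the series of the genome-wide background, compared with 74.2% on the major arms (72.5 to 75.8), or 8.63% and 78.1% with a wider tolerance of 0.015, as a local input above that background would give. The explanation arose from these shares, so they do not count as a test of it. Whether the copies on Uextra repeat a placed site, and whether the scaffold ends limit the width of the peaks, stays open, since no sequence of release 5 was used here. No biological explanation was tested, because the design has a single antibody and stage.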

How the results depend on the processing

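Rotation of the arm labels, windows of 1 Mb, joining and 1 Mb placement for the spacing, the correlations within the major arms and within Uextra, and the wider tolerances and the 1 Mb stretches for the score series were chosen after seeing the data. In all, 61 alternatives were computed, and 52 kept direction and side of the threshold. The density of 2R lost its call in windows of 1 Mb (ratio 1.33) and under rotation (1.37), with adjusted permutation p-values from 0.0003 to 0.37 over its alternatives. The lower density of X against the other major arms lost its call in windows of 200 kb (ratio 0.763) and 1 Mb (0.778), among the peaks ranked above the median (0.744) or the upper quartile (0.695) of the score, and under rotation (0.764), with adjusted permutation p-values from 0.010 to 0.42. Against the autosomes alone the call was lost in windows of 1 Mb (0.769) and under rotation (0.759), with permutation p-values from 0.0029 to 0.14. No alternative turned a direction, but the rotation and the permutation of 1 Mb stretches keep the same ratio or difference and could not turn it. The cause of the lost calls was not tested. With no difference simulated and peaks clustered about as observed, the test of single windows called X in 21% of draws. The share of neighbours over that of random placements ran from 1.96 (within 10 kb) to 5.35 (within 2 kb). The share on the score series was higher on X by 24.2 percentage points with a tolerance of 0.01 and by 24.8 with 0.015. No paired analysis was possible because the list has no columns for single libraries, and leaving out a replicate was not possible for the same reason. The alternatives for transcription start sites, annotation classes, gene lists, homeotic complexes, promoter and distal peaks and motifs were not run, because no genome or annotation of release 5 was used here. The depth of the libraries is unknown, so stretches without a peak are not shown to lack Cmi.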

Other observations

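The tests of the score series on X, the joining and 1 Mb placement for the spacing, and the tests of the peaks off the common score series were chosen only after the data had been seen, the first of these after its own result; the density of X among the highest-scoring peaks was set before the data were examined, but weighed here, and recomputed in windows of 1 Mb, after its value had been seen.

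Some Cmi peaks were wide. After the peak of 5398 bp on 2L, the widest were on 3L at 16400415 to 16405113 (4699 bp, score 58.5), on 3R at 7602759 to 7606812 (4054 bp, score 100.4), on 3L at 14749263 to 14753291 (4029 bp, score 41.6) and on 2L at 5977026 to 5980962 (3937 bp, score 35.4). On X a group of 8 peaks covered 79.8% of the stretch from 1837514 to 1846579, and a group of 11 peaks on 2R covered 64.9% of the stretch from 18563716 to 18578811, with a top score of 100.4. Peaks also lay at the start of assembled sequences. The first peak of 3R ran from base 50 to 1198 (score 20.5), and the only peak of 2RHet ran from base 14 to 287 (score 50.8).

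The lower density of peaks on X was weighed, with the reservation that its call was lost when neighbouring windows were kept together (ratio 0.759), while 1.5% of draws with equal densities and peaks clustered about as observed reached that ratio or a lower one, so chance stays open. A loss of only the peaks near the score threshold is argued against: among the peaks ranked above the upper quartile of the score the ratio of X to the autosomes was 0.692 (95% interval 0.517 to 0.911, windows resampled), and in windows of 1 Mb it was 0.701 (0.491 to 0.948). Scores lowered across X as a whole could also give such a ratio, so the ratio cannot speak to that. An X input below the genome-wide background stays open: the share of peaks on the common score series was 24.9 percentage points higher on X than on the autosomes (two-sided permutation p = 1e-05, the smallest that 100000 permutations can give, n = 131 and 636 windows with peaks), and permuting 22 and 96 stretches of 1 Mb gave the same p. The explanation arose from this share, which is therefore no test of it, and the reads of the input libraries were not used here. The number of copies of X in the embryos, for which no correction was made, was not weighed and also stays open. No biological explanation was tested. The read heights on the series gave no clear difference, with medians of 84 reads on X (n = 377 peaks) and 86 on the autosomes (n = 1598 peaks, permutation p = 0.30). Only called peaks on the series enter this comparison, and none of them is lower than 63 reads. It therefore says little about signal too low to be called.

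The spacing of the peaks was set against 2 explanations. If the caller had only split single regions at gaps of up to 1 kb, joining peaks whose edges lie within 1 kb would have removed the grouping. But 35.0% of the 1974 joined regions still had a neighbour within 5 kb, against at most 19.4% in 1000 random placements. Splits of broad regions at wider gaps are not undone by this joining and stay open. If the spacing came only from stretches of 1 Mb with more or fewer peaks, placement within such stretches would have matched it, but the observed share was 2.69 times the mean of those placements, which reached at most 27.0%. No biological explanation was tested.

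The scores of 668 autosomal peaks (29.5%) lay off the common series, among them peaks with recurrent values that narrowly miss a step, and 579 (25.6%) did with a tolerance of 0.015. Of 978 neighbouring pairs within 5 kb, 67.9% had the same status, above the highest of 1000 shuffles within arms (63.1%), and with the wider tolerance it was 70.0% against 66.8%. The share off the series was 28.6% for peaks with a neighbour (n = 1460 peaks) and 31.0% for isolated peaks (n = 806 peaks), a difference of -2.39 percentage points that did not pass (permutation p = 0.33, the classes swapped within windows), nor did it with the wider tolerance (-2.51, permutation p = 0.28).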
